A study of Oryzias latipes with 48 samples.

How the data were processed

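RNA was measured in medaka (Oryzias latipes) tissue that held the ventral telencephalon, the hypothalamus and the pituitary. Per the labels, fish lived outdoors under natural conditions and were sampled every 4 h over 24 h at the equinoxes and solstices. Each of the 4 seasons has 6 clock hours (2, 6, 10, 14, 18 and 22) with 2 libraries each, which gives 48 libraries in 24 groups and 12 libraries per season. The labels describe poly-A selected, strand-specific, paired-end libraries. The number of fish in a library, their sex, and the year, collection and library batch of each season are not given in the sources used here. Nothing states that libraries came from separate fish, so p-values measure the spread between libraries.

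The authors deposited 1 table of FPKM values (fragments scaled to transcript length and library total) for 26167 genes and 48 libraries. Bowtie2 2.2.5 and RSEM 1.2.12 are named per the submitters' processing notes. The genome build and the annotation are not given in the sources used here. Values carry 2 decimals, the smallest value above 0 is 0.01, and 9.23% of values are 0. Read counts were not used here, so the depth of each library is unknown and no counting interval can be given. The FPKM sum per library lay between 314605 and 359311, and between 23521 and 23943 genes were above 0. Ratios of low values between libraries had only weak peaks (1.53 to 3.85 times the median bin), which do not give relative depth.

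Gene IDs were matched to a reference table of gene names, which covered 25080 of the 26167 IDs. The table served for names alone. A further 945 entries are unannotated transcripts without a gene name. In total 273 genes share every value with another gene, 10 of them among the genes tested. Closely related copies (tubulins, histones, hemoglobins, ubiquitin ligases) may share reads, so their separate values are less certain than those of single-copy genes.

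Genes with a mean FPKM of at least 1 over the 48 libraries were tested, which left 16622. Values were taken as log2(FPKM + 1) with no further scaling. Fold values are 2 to the power of the difference on this scale, so they understate the change of genes near or below 1 FPKM. They compare means of log2 values, which a wide daily range lowers against the mean FPKM. For genes with a wider range in 1 season, folds between seasons mix level with daily range. Tests used limma 3.58.1 in R 4.3.3 with an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method over the 16622 genes of each test. A gene counts as called when its adjusted p is below 0.05. Season differences compare the mean of the 6 clock hours in a season with that in another, in a model of the 24 groups with 24 residual degrees of freedom. Daily rhythms were tested with a cosine curve of 24 h period in each season, with 36 residual degrees of freedom. The amplitude is given on the log2 scale from the mean to the peak, and the fold from trough to peak. Rhythm differences test whether the curves differ in amplitude or peak hour between seasons. Tests are two-sided. Sampling every 4 h allows no finer timing than the fitted curve gives, and other curve shapes are missed by the cosine test. Each season covers 1 cycle of 24 h, so a daily rhythm cannot be told from a drift over the sampling.

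Before the data were examined, the comparisons, the tests, the alternatives, the gene lists and the rule for naming genes were fixed. Lists covered clock genes, hormones and neuropeptides, stress responses, metabolism and markers of cell types. Members were found by symbol and product name. After reading the names of the matches, 40 entries were removed and 8 added before any test was run. Of 32 lists with members in the file, 30 had at least 4 tested members and were tested. Lists were compared between seasons with camera in limma, with the correlation between genes estimated for each list, over 180 tests (30 lists, 6 season pairs). Counts of list members are also given adjusted over the list alone. The share of rhythmic members, from the curve averaged over seasons, was compared with that of other tested genes by Fisher's exact test over 30 lists. Fisher's exact test treats genes as independent replicates, which they are not.

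Genes were named by a rule. Any tested list member could be named. For summer against winter and spring against autumn, the rule took the 10 highest and the 10 lowest fold changes, and for each other season pair the 3 highest and 3 lowest. These had to be called, reach 5 FPKM in the higher season, carry a gene or product name, and show no overlap between the 12 libraries of a season and the 12 of the other. For rhythms, the 10 smallest p of the mean curve and of the difference over any season were taken, and the 5 smallest p of each season and of the other differences.

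Alternatives were a pseudocount of 0.1, no filter on low values, scaling by median ratios, quantile normalization, array weights, a fit of the compared seasons alone, a clock hour factor in place of the cosine (and the reverse for season tests), a replicate block, each library left out in turn, and camera with a preset correlation of 0.01. Leaving out 3 spring libraries together was added after seeing the data. For each test, 100 regroupings of the libraries, the real one included, were compared. The pipeline was tested on simulated data with 16622 genes. Noise was drawn independently for each gene, and 76, 58 and 66 genes were changed by 0.25, 0.5 and 1. In the data most genes differ between seasons and genes are correlated, so the rates below need not hold there. Season differences of 0.25, 0.5 and 1 on the log2 scale were recovered in 64.5%, 98.3% and 98.5% of changed genes with 7 false calls. Rhythms of those amplitudes were recovered in 61.8%, 94.8% and 98.5% with 7 false calls and a median error of 0.217 h in the peak hour. Rhythm differences were recovered in 44.7%, 89.7% and 98.5% with 5 false calls. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.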

Results

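Gene expression was measured by RNA sequencing in medaka, a small freshwater fish that breeds seasonally, in a tissue block that holds the ventral telencephalon, the hypothalamus and the pituitary. The 48 libraries cover the spring equinox, the summer solstice, the autumn equinox and the winter solstice, with 12 libraries per season, 2 at each of 6 clock hours. The series was set up to follow the daily profile of each gene in each season, and it also allows season levels to be compared. Levels are FPKM (fragments scaled to transcript length and library total), given as mean ± SD over n = 12 libraries of a season. SE is the standard error of a fitted log2 difference or amplitude, unless stated otherwise. Depth per library is not given; FPKM sums lay between 314605 and 359311. The correlation across genes between the 2 libraries of a group was 0.977 to 0.988 (median 0.986), where genes are not independent replicates.

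Season was the main axis along which the tissue differed. Libraries of summer and autumn lay on 1 side of the first principal component (42.7% of variance; scores 24.2 to 33.6 in summer and 18.2 to 29.4 in autumn) and those of spring and winter on the other (scores -29.5 to -21.4 in spring and -28.6 to -23.1 in winter). Among the tested genes, the median share of variance was 49.5% for season, 5.9% for clock hour, 20.5% for the season-by-hour part and 18.3% between the 2 libraries of a group. These parts have 3, 5, 15 and 24 degrees of freedom, so the shares are not comparable as they stand. Of 16622 tested genes, 15117 (90.9%) differed between any seasons. For 10835 of these (71.7%) the summer and autumn means fell on 1 side and the spring and winter means on the other, against 3108 (20.6%) for summer with spring and 1174 (7.8%) for summer with winter. Markers of several cell types moved along this axis. The SE of the medians below comes from resampling the genes of a list, so it leaves out the spread between libraries. The median log2 difference, summer and autumn minus spring and winter, was 0.28 (SE 0.03) for 26 neuron markers, 0.51 (SE 0.20) for 19 myelin markers, 0.69 (SE 0.29) for 11 red blood cell markers, 0.18 (SE 0.10) for 16 radial glia markers, 0.18 (SE 0.07) for 19 microglia and macrophage markers and -0.001 (SE 0.06) for 18 endothelial markers, against 0.06 for all genes. The 3 spring libraries from clock hour 2 (library 1), clock hour 18 (library 1) and clock hour 22 (library 2) lay at 21.1 or above on the second component (9.8% of variance), the other 9 spring libraries at 13.9 or below. Year, collection and library batch of each season are not given, so season and batch cannot be told apart.

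**Figure D1:**
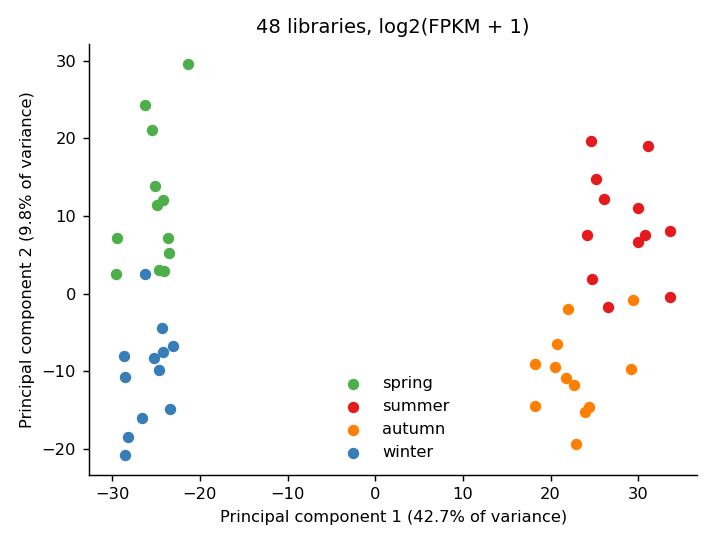
Scores of the 48 libraries (points, coloured by season) on the first 2 principal components of log2(FPKM + 1), with the percent of variance on each axis. The summer and autumn libraries all score 18.2 or more on the first component and the spring and winter libraries -21.4 or less.

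In summer, several genes of reproduction stood above their winter level, while their list as a whole did not pass its test. The transcript of lhb, the beta subunit of luteinizing hormone, was at 157 ± 56.2 FPKM in summer and 7.14 ± 1.42 in winter, an 18.6-fold difference (log2 4.22, SE 0.12, adjusted p = 1.1e-21). cyp19b, the brain aromatase that makes estrogens from androgens, was 4.91-fold higher (416 ± 72.3 against 83.3 ± 10.7 FPKM; SE 0.07, adjusted p = 8.9e-22). gnrh1, the releasing hormone that drives gonadotropin secretion, was 2.70-fold higher (5.27 ± 1.91 against 1.27 ± 0.456 FPKM; SE 0.15, adjusted p = 7.6e-10). In the other direction, the cryptochrome-1 gene LOC101160902, a repressor in the circadian clock, was 7.86-fold lower in summer (3.47 ± 2.89 against 28.9 ± 5.38 FPKM; SE 0.08, adjusted p = 2.1e-22).

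Of 16622 genes, 6986 were higher and 5465 lower in summer than in winter, and 551 of them differed at least 2-fold (284 higher, 267 lower). The share higher was 56.1% with the FPKM as deposited, 51% after median-ratio scaling and 51.4% after quantile normalization. The rule for the 20 genes taken by rank required that the 12 libraries of a season not overlap the 12 of the other. Besides lhb and cyp19b, the 10 highest were f13a1, a subunit of the coagulation factor that cross-links fibrin (16.1-fold), a peptide YY-like gene (LOC101160582, 7.43-fold), a sodium- and chloride-dependent transporter (LOC101161687, 6.54-fold), the neuropeptide B gene npb_105354556 (5.28-fold, 327 ± 57.4 against 61.4 ± 12.3 FPKM), a pancreatic alpha-amylase (LOC101163630, 5.25-fold), a tubulin alpha chain (LOC101168810, 5.10-fold), a dimethylaniline monooxygenase (LOC101173929, 4.38-fold) and an SDR family dehydrogenase (LOC101157874, 4.06-fold). Besides LOC101160902, the 10 lowest were the cartilage matrix gene matn3 (7.71-fold lower), an E3 ubiquitin ligase of the RNF type (LOC101171057, 7.37-fold) and another (LOC101163418, 5.51-fold), meprin A subunit alpha (LOC101173759, 6.86-fold), isyna1, which makes inositol phosphate (6.54-fold, 72.2 ± 31.0 against 441 ± 65.7 FPKM), jpt2 (6.17-fold), a histone H2B (LOC111947380, 5.75-fold), kcnj8, a potassium channel subunit (5.44-fold), and the transmembrane gene LOC101156305 (5.10-fold). The SE of these log2 differences was 0.05 to 0.16, and the largest adjusted p was 4.4e-13.

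Among 10 pituitary hormone genes, 5 were higher in summer, 3 lower and 2 not called (5 and 3 adjusted over the list alone; camera adjusted p = 0.85). fshb, the beta subunit of follicle-stimulating hormone, was 2.03-fold higher (183 ± 46.0 against 89.3 ± 22.4 FPKM), and cga, the alpha subunit that both gonadotropins share, 2.18-fold higher (760.4 ± 134 against 355 ± 106). Somatolactin (LOC100049402), a fish hormone related to growth hormone, was 3.06-fold higher (197 ± 56.5 against 72.8 ± 46.0), while growth hormone itself (LOC101171460) was 1.89-fold lower (1277 ± 254 against 2467 ± 712). Among 20 genes of the reproductive neuroendocrine list, 11 were higher, 5 lower and 4 not called (11 and 5 adjusted over the list alone; camera adjusted p = 0.805). They include fst, whose product follistatin binds activin (1.99-fold higher, 4.22 ± 0.355 against 1.63 ± 0.235). The appetite list had 9 of 17 members higher and 4 lower (9 and 4 adjusted over the list alone; camera adjusted p = 0.906). A CART gene (LOC100533500), of a family of appetite-reducing peptides, was 2.56-fold lower in summer (2.96 ± 1.30 against 8.93 ± 2.39). The thyroid and photoperiod list was split, with 8 higher, 8 lower and 5 not called of 21 (8 and 8 adjusted over the list alone; camera adjusted p = 0.955). Of 14 neurohypophysial and releasing peptide genes, 3 were higher and 3 lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.952), and tac1, the tachykinin precursor, was 2.03-fold lower (43.7 ± 8.49 against 89.3 ± 11.7).

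Most clock repressors and activators had a lower mean log2 level in summer than in winter. Their wider daily range in summer, given below, lowers that mean, so their folds mix level with daily range. A fold can therefore exceed the ratio of the mean FPKM beside it. Of 17 clock repressors, 4 were higher and 13 lower in summer (4 and 13 adjusted over the list alone; camera adjusted p = 0.354). The circadian-associated transcriptional repressor LOC101172421 was 4.63-fold lower (18.7 ± 16.7 against 58.3 ± 5.97 FPKM) and the period 2 gene LOC101161338 3.16-fold lower, whereas another cryptochrome-1 gene, LOC101164536, was 2.42-fold higher (39.8 ± 21.5 against 13.8 ± 1.496). Of 11 clock activators, 0 were higher, 7 lower and 4 not called (0 and 7 adjusted over the list alone; camera adjusted p = 0.174), with the ROR-beta-like receptor LOC101170052 2.63-fold lower (23.4 ± 16.1 against 50.7 ± 4.65). The NFIL3 gene LOC101175377, 1 of 8 PAR bZIP clock output genes, was 2.95-fold lower; that list had 3 higher and 5 lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.69). Light and DNA repair genes were 3 higher, 6 lower and 1 not called of 10 (3 and 6 adjusted over the list alone; camera adjusted p = 0.445).

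Most markers of neurons and myelin were higher in summer. Of 26 neuron markers, 22 were higher, 0 lower and 4 not called (22 and 0 adjusted over the list alone; camera adjusted p = 0.354). Of 19 myelin markers, 13 were higher, 2 lower and 4 not called (15 and 2 adjusted over the list alone; camera adjusted p = 0.332). The myelin gene mpz was 2.67-fold higher (209 ± 25.9 against 77.7 ± 9.72 FPKM) and the proteolipid protein gene LOC101157800 2.05-fold higher. Microglia and macrophage markers were 13 higher and 2 lower of 19 (13 and 2 adjusted over the list alone; camera adjusted p = 0.69). Red blood cell markers were 8 higher and 1 lower of 11 (8 and 1 adjusted over the list alone; camera adjusted p = 0.701), with the hemoglobin gene gb_101171201 2.502-fold higher (442 ± 133 against 179.9 ± 66.3).

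Most proteasome genes were lower in summer. Of 38 proteasome genes, 27 were lower and 5 higher (27 and 6 adjusted over the list alone; camera adjusted p = 0.445). Of 88 ribosomal protein genes, 51 were lower and 11 higher, against 39 and 21 after quantile normalization (50 and 11 adjusted over the list alone; camera adjusted p = 0.767). Oxidative phosphorylation genes were 41 higher and 13 lower of 82 (41 and 13 adjusted over the list alone; camera adjusted p = 0.904). The cold and heat list was 6 higher and 12 lower of 21 (6 and 12 adjusted over the list alone; camera adjusted p = 0.576). Against the latter, hsf1, the master regulator of heat shock genes, was 1.89-fold higher in summer (66.0 ± 17.2 against 33.4 ± 1.26 FPKM). The ER stress list was 9 higher and 5 lower of 20 (9 and 5 adjusted over the list alone; camera adjusted p = 0.923). The fatty acid list was split, 11 higher and 10 lower of 21, a majority that scaling turned (11 and 10 adjusted over the list alone; camera adjusted p = 0.85). Its acyl-CoA desaturase gene LOC105353580, which makes monounsaturated fatty acids, was 2.45-fold lower in summer (23.9 ± 2.34 against 60.03 ± 4.33 FPKM). No list passed the camera test between summer and winter. The median, the mean and the test did not share a sign for the neurohypophysial, thyroid, fatty acid, interferon, endothelial and retina lists. Scaling also turned the majority and median of the endothelial list and the median of the neurohypophysial list.

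**Figure D2:**
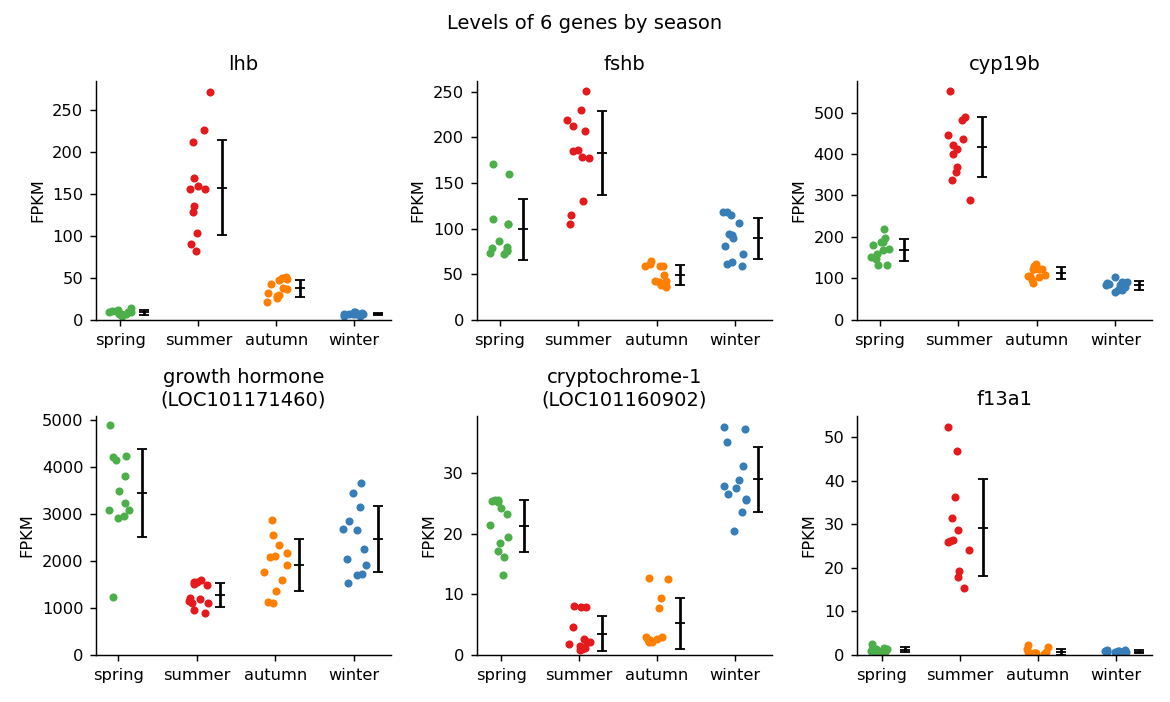
FPKM (y axes, starting at 0) of 6 genes in the 12 libraries of each season (points), with mean ± SD at the right of each group (bars). lhb reaches 157 ± 56.2 in summer against 7.14 ± 1.42 in winter, while the growth hormone gene averages 1277 in summer and 3437 in spring.

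Spring and autumn, the equinox dates, differed about as widely as summer and winter. The hemoglobin gene gb_101171201 was 6.20-fold lower in spring (69.4 ± 17.6 against 432 ± 99.3 FPKM; log2 -2.63, SE 0.13, adjusted p = 9.3e-17). lhb was 3.95-fold lower (8.85 ± 2.76 against 37.7 ± 10.1; SE 0.12, adjusted p = 3.0e-14), while fshb was 1.96-fold higher in spring (99.4 ± 33.5 against 49.2 ± 10.7; SE 0.13, adjusted p = 2.3e-07). pomc, the precursor of ACTH and melanocortins, was 2.69-fold lower in spring (212 ± 48.5 against 581 ± 208; SE 0.13, adjusted p = 4.8e-11), and growth hormone 1.78-fold higher (3437 ± 936 against 1919 ± 553; SE 0.15, adjusted p = 1.2e-05). The cryptochrome-1 gene LOC101160902 was 4.23-fold higher in spring (21.2 ± 4.29 against 5.18 ± 4.18).

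In total 4542 genes were higher and 7496 lower in spring than in autumn, and 418 differed at least 2-fold (207 higher, 211 lower). The split of the calls rests on scaling: 37.7% of called genes were higher in spring with the FPKM as deposited, 50% after median-ratio scaling (5917 higher, 5926 lower) and 48.4% after quantile normalization (5722 higher, 6096 lower). The 10 highest by rank were a histone H2B (LOC111947380, 6.72-fold), matn3 (6.66-fold), a suppressor of cytokine signaling (LOC101165453, 5.29-fold), meprin A subunit alpha (LOC101173759, 5.21-fold), tensin-2 (LOC101172728, 5.17-fold), slain1 (5.06-fold), trichohyalin (LOC105356162, 4.94-fold), a cartilage intermediate layer protein (LOC101173877, 4.91-fold), the ectodysplasin receptor edar (4.77-fold) and a histone H2A (LOC101158068, 4.72-fold). LOC101173877 was variable in spring (6.75 ± 7.60 FPKM) and near 0 in autumn (0.0417 ± 0.0851). Besides gb_101171201 and lhb, the 10 lowest were fetuin-B (LOC101173833, 8.09-fold lower), the transporter LOC101161687 (6.997-fold), tubulins (LOC101160296, 6.49-fold; LOC101157969, 4.78-fold; LOC101168810, 4.64-fold), an interferon alpha-inducible protein (LOC110017567, 4.97-fold), a claudin-4-like gene (LOC101165395, 4.64-fold) and dnajc8 (3.68-fold). The SE of these differences was 0.05 to 0.18.

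Most oxidative phosphorylation and ER stress genes were lower in spring than in autumn. Of 82 oxidative phosphorylation genes, 72 were lower, 1 higher and 9 not called (73 and 1 adjusted over the list alone; camera adjusted p = 0.445). Of 20 ER stress genes, 17 were lower, 0 higher and 3 not called (17 and 0 adjusted over the list alone; camera adjusted p = 0.174). Among them were pdia3, a disulfide isomerase (2.299-fold lower, 13.1 ± 1.59 against 31.5 ± 4.74 FPKM), and a calreticulin gene, LOC101162115, a calcium-binding chaperone (1.85-fold lower). Of 21 cold and heat genes, 14 were lower and 2 higher (14 and 2 adjusted over the list alone; camera adjusted p = 0.445), with cirbp, an RNA-binding protein induced by cold, 1.44-fold lower in spring (799.8 ± 60.6 against 1162 ± 198). Proteasome genes were 28 lower and 3 higher of 38 (28 and 3 adjusted over the list alone; camera adjusted p = 0.623). Ribosomal protein genes were 41 lower and 9 higher of 88, but 20 and 20 after median-ratio scaling and 19 and 18 after quantile normalization (37 and 9 adjusted over the list alone; camera adjusted p = 0.93). Microglia and macrophage markers were 7 higher and 3 lower in spring of 19, with a median whose sign scaling turned (7 and 3 adjusted over the list alone; camera adjusted p = 0.767). Neuron markers were 20 lower and 1 higher of 26 (20 and 1 adjusted over the list alone; camera adjusted p = 0.445). Myelin markers were 14 lower and 2 higher of 19 (14 and 2 adjusted over the list alone; camera adjusted p = 0.354). Red blood cell markers were 8 lower and 3 higher of 11 (8 and 3 adjusted over the list alone; camera adjusted p = 0.645). In the myelin list, mpz was 2.84-fold lower (89.6 ± 12.1 against 256 ± 32.4) and LOC101157800 2.67-fold lower (188 ± 20.7 against 502 ± 49.7).

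Clock genes and hormones also differed between the equinoxes. The wider daily range of clock genes in autumn lowers their mean log2 level, so their folds mix level with daily range. Of 11 clock activators, 8 were higher in spring and 0 lower (8 and 0 adjusted over the list alone; camera adjusted p = 0.174). Of 17 clock repressors, 11 were higher and 2 lower (11 and 2 adjusted over the list alone; camera adjusted p = 0.282), LOC101172421 being 3.73-fold higher (72.4 ± 26.7 against 25.4 ± 19.4 FPKM), and of 10 light and DNA repair genes 7 were higher and 1 lower (7 and 1 adjusted over the list alone; camera adjusted p = 0.174). The ROR-beta-like receptor LOC101170052 was 2.19-fold higher in spring and the NFIL3 gene LOC101175377 2.11-fold. Pituitary hormone genes were 5 higher and 4 lower of 10 (5 and 4 adjusted over the list alone; camera adjusted p = 0.923): cga was 1.60-fold and cyp19b, of the reproductive list, 1.48-fold higher in spring, while a thyrotropin beta gene (LOC105354380) was 2.53-fold lower (0.406 ± 0.110 against 4.09 ± 5.09). Neurohypophysial and releasing peptide genes were 10 lower and 1 higher of 14 (10 and 1 adjusted over the list alone; camera adjusted p = 0.645), the isotocin gene LOC101160739, the fish counterpart of oxytocin, being 2.097-fold lower in spring (162 ± 41.1 against 334 ± 49.2). No list passed the camera test. The median, the mean and the test did not share a sign for the PAR bZIP, opsin, endothelial, interferon, microglia, pituitary and reproductive lists, and scaling turned the median or the majority of all of these but the pituitary list.

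The summer-winter and autumn-spring differences were related across genes (Pearson r = 0.69, Spearman rho = 0.65; genes are not independent replicates). Of 9534 genes called in both, 8261 (86.6%) had the same direction. Higher in summer and in autumn were 5104, and lower in both 3157, against 3150 and 1493 if calls in the 2 comparisons were independent over all 16622 tested genes. Both tests use the same spread for a gene, so their calls are not independent. The counts hold for the FPKM as deposited and were not repeated after scaling. Median-ratio scaling left 51% of the calls higher in summer than in winter and 50% higher in spring than in autumn, so the excess of 5104 over 3157 may rest on scaling.

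Between spring and summer, lhb and a peptide YY-like gene were higher in summer, while growth hormone was higher in spring. lhb was 15.7-fold higher in summer than in spring (log2 difference, spring minus summer, -3.98, SE 0.12, adjusted p = 4.9e-21), f13a1 13.4-fold and the peptide YY-like gene LOC101160582 7.66-fold higher. The histone H2B gene LOC111947380 (7.66-fold), matn3 (6.998-fold) and the ubiquitin ligase LOC101163418 (6.92-fold, 189 ± 20.9 against 28.7 ± 11.9 FPKM) were higher in spring. The growth hormone gene LOC101171460 averaged 3437 FPKM in spring and 1277 in summer. Pituitary hormone genes were 4 higher and 5 lower in spring of 10 (4 and 5 adjusted over the list alone; camera adjusted p = 0.99). In total 4967 genes were higher and 7299 lower in spring, 226 and 232 of them at least 2-fold. The imbalance rests on scaling, with 5974 higher and 6100 lower after median-ratio scaling and 5915 and 6187 after quantile normalization. Of 26 neuron markers, 23 were lower and 0 higher in spring (23 and 0 adjusted over the list alone; camera adjusted p = 0.285). Of 11 red blood cell markers, 10 were lower and 1 higher (10 and 1 adjusted over the list alone; camera adjusted p = 0.445). Of 20 ER stress genes, 17 were lower and 1 higher (17 and 1 adjusted over the list alone; camera adjusted p = 0.198). Of 82 oxidative phosphorylation genes, 65 were lower and 3 higher (65 and 3 adjusted over the list alone; camera adjusted p = 0.576). Clock activators were 8 higher and 0 lower of 11 (8 and 0 adjusted over the list alone; camera adjusted p = 0.119). Repressors were 13 higher and 2 lower of 17 (13 and 2 adjusted over the list alone, camera adjusted p = 0.213). The counts of both clock lists mix level with the wider daily range in summer.

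Between summer and autumn, lhb, fshb, cyp19b and gnrh1 were lower in autumn. lhb was 3.99-fold higher in summer than in autumn (log2 2.00, SE 0.12, adjusted p = 1.2e-12), fshb 3.62-fold, cyp19b 3.61-fold (416 ± 72.3 against 114 ± 14.1 FPKM), gnrh1 3.22-fold, f13a1 17.1-fold and LOC101160582 4.68-fold. pomc was 1.60-fold lower in summer, and cyp26b1, which breaks down retinoic acid, 3.55-fold lower (1.66 ± 0.392 against 8.70 ± 2.55), followed by a cytochrome c oxidase subunit 8 gene (LOC101157431, 2.55-fold) and GTP cyclohydrolase 1 (LOC101161367, 2.21-fold). The reproductive list was 6 higher, 4 lower and 10 not called in summer of 20 (7 and 4 adjusted over the list alone; camera adjusted p = 0.617), and pituitary hormone genes 4 higher and 5 lower of 10 (4 and 5 adjusted over the list alone; camera adjusted p = 0.923). In total 3221 genes were higher and 4024 lower in summer, 21 and 24 of them at least 2-fold. Median-ratio scaling turned this majority (3721 higher, 3510 lower), and quantile normalization left 3557 higher and 3645 lower. Ribosomal protein genes were 73 lower and 0 higher in summer of 88, against 33 and 0 after quantile normalization (78 and 0 adjusted over the list alone; camera adjusted p = 0.445). Proteasome genes were 33 lower and 0 higher of 38 (33 and 0 adjusted over the list alone; camera adjusted p = 0.174). Oxidative phosphorylation genes were 38 lower and 0 higher of 82 (38 and 0 adjusted over the list alone; camera adjusted p = 0.601). Immediate-early genes were 17 higher and 2 lower of 27 (17 and 2 adjusted over the list alone; camera adjusted p = 0.29).

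Between autumn and winter, the transporter LOC101161687 (6.46-fold, log2 2.69, SE 0.09, adjusted p = 1.4e-20), a tubulin alpha-1C-like gene (LOC101160296, 5.58-fold) and fetuin-B (LOC101173833, 5.403-fold, 20.1 ± 6.75 against 2.96 ± 1.51 FPKM) were higher in autumn. matn3 (7.33-fold), meprin A subunit alpha (LOC101173759, 7.32-fold) and the ubiquitin ligase LOC101171057 (5.76-fold) were higher in winter. In total 7051 genes were higher and 4863 lower in autumn, 173 and 221 of them at least 2-fold. The imbalance rests on scaling, with 5927 higher and 5870 lower after median-ratio scaling and 6146 and 5681 after quantile normalization. Myelin markers were 16 higher and 2 lower in autumn of 19 (16 and 2 adjusted over the list alone; camera adjusted p = 0.198). Neuron markers were 20 higher and 3 lower of 26 (21 and 3 adjusted over the list alone; camera adjusted p = 0.445). Oxidative phosphorylation genes were 57 higher and 10 lower of 82 (57 and 10 adjusted over the list alone; camera adjusted p = 0.692). Light and DNA repair genes were 1 higher and 8 lower of 10 (1 and 8 adjusted over the list alone; camera adjusted p = 0.174).

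Between winter and spring, chaperone genes differed. In winter the inducible HSP70 gene LOC111947723 was 3.09-fold higher than in spring (7.22 ± 4.28 against 1.45 ± 0.618 FPKM; log2 1.63, SE 0.10, adjusted p = 6.6e-13), the DnaJ gene LOC101166714 2.43-fold (22.0 ± 4.42 against 8.43 ± 1.78), the HSP90-alpha gene LOC101169506 2.42-fold (66.6 ± 9.95 against 26.8 ± 3.65) and hspa5, the main chaperone of the endoplasmic reticulum, 1.68-fold (124 ± 8.55 against 73.0 ± 6.44; adjusted p = 4.8e-18). Of 20 ER stress genes, 18 were higher in winter, 1 lower and 1 not called (18 and 1 adjusted over the list alone), and this list passed camera (adjusted p = 0.0153). Of 21 cold and heat genes, 15 were higher, 1 lower and 5 not called (15 and 1 adjusted over the list alone), and this list passed camera (adjusted p = 0.0479). pdia3, of the ER stress list, was 1.55-fold higher in winter. These are the only 2 of 180 list tests called with the estimated correlation; with a preset correlation of 0.01, 46 were called.

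Other genes and lists also had members called between winter and spring. A tubulin alpha gene (LOC101171518) was 2.104-fold higher in winter (666 ± 66.3 against 317 ± 45.0 FPKM), whereas LOC101173877 (4.83-fold), a ferritin gene (LOC101171335, 2.73-fold, 4.22 ± 1.27 against 13.4 ± 5.03) and the thyrotropin beta-like gene LOC101171658 (2.26-fold, 23.4 ± 5.82 against 56.1 ± 22.6) were lower. cyp19b was 2.01-fold lower in winter and the isotocin gene LOC101160739 1.54-fold higher. All 14 neurohypophysial and releasing peptide genes were higher in winter (14 adjusted over the list alone; camera adjusted p = 0.174). Oxidative phosphorylation genes were 59 higher and 0 lower of 82 (63 and 2 adjusted over the list alone; camera adjusted p = 0.422). Proteasome genes were 31 higher and 2 lower of 38 (32 and 2 adjusted over the list alone; camera adjusted p = 0.212). Cholesterol synthesis genes were 17 higher and 0 lower of 27 (17 and 0 adjusted over the list alone; camera adjusted p = 0.332). Red blood cell markers were 7 higher and 0 lower of 11 (7 and 0 adjusted over the list alone; camera adjusted p = 0.356). Microglia and macrophage markers were 11 lower and 0 higher of 19 (14 and 0 adjusted over the list alone; camera adjusted p = 0.198). In total 4670 genes were higher and 3534 lower in winter, 18 and 28 of them at least 2-fold. Scaling turned this majority, with 4013 higher and 4179 lower after median-ratio scaling and 4025 and 4174 after quantile normalization.

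Genes of the circadian clock had daily rhythms of wide range in summer and autumn. bhlhe41, a clock repressor, had an amplitude of 1.48 on the log2 scale in summer (SE 0.04, 7.76-fold from trough to peak, peak at hour 4.27, adjusted p = 6.3e-26) and 1.62 in autumn (SE 0.04, 9.40-fold, peak at hour 5.65, adjusted p = 2.0e-27). In spring and winter its amplitude was 0.06 (SE 0.04, adjusted p = 0.64) and 0.05 (SE 0.04, adjusted p = 0.75). The nuclear receptor gene LOC101173939 (NR1D1, a repressor of clock activator genes) had a 15.6-fold daily range in summer, with a peak at hour 0.53, and a 17.8-fold range in autumn, with a peak at hour 1.95. In spring and winter its range was 1.34-fold and 1.32-fold, with adjusted p of 0.24 and 0.32. The clock activator LOC101159313 (ARNT-like protein 1) peaked on the opposite side of the day, at hour 16.6 in summer (4.04-fold) and hour 18.3 in autumn (4.87-fold).

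The other genes with the smallest p of the mean rhythm were the PAR bZIP factor LOC101163688 (hepatic leukemia factor, 12.3-fold in summer, with a peak at hour 3.02), the ROR-beta-like receptor LOC101170052 (6.82-fold and 4.87-fold), the period 3 gene LOC101159817 (4.00-fold and 4.09-fold), LOC101172430 (NPAS2, 3.18-fold and 3.51-fold), LOC101174183 (ARNT-like protein 2, 4.31-fold and 4.32-fold), a WD40 repeat gene (LOC101168770, 8.13-fold and 8.52-fold) and LOC101157237 (CLOCK-interacting pacemaker, 8.001-fold and 8.32-fold). per1 had a 6.82-fold range in summer, with a peak at hour 4.67, and a 7.74-fold range in autumn, with a peak at hour 4.92. per2, induced by light in fish, ranged 4.15-fold in summer with a peak at hour 12.2 and 4.12-fold in autumn with a peak at hour 13.1. lonrf1, also on the light list, ranged 3.91-fold and 3.81-fold with peaks at hours 12.8 and 12.7. A second NR1D1 gene (LOC101174341) ranged 13.8-fold in summer, and LOC101172421 16.9-fold in summer and 12.4-fold in autumn. The SE of these amplitudes was 0.04 to 0.13, and each adjusted p in summer and autumn was 4.1e-09 or less.

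By list, all 11 clock activators were rhythmic in summer and in autumn and 0 in spring and winter (11, 11, 1 and 0 adjusted over the list alone for summer, autumn, spring and winter). For 17 clock repressors the counts were 17 in summer, 15 in autumn, 2 in spring and 0 in winter (17, 16, 2 and 1 adjusted over the list alone), and for 8 PAR bZIP genes 8, 8, 0 and 0 (8, 8, 5 and 0 adjusted over the list alone). Light and DNA repair genes had 10, 9, 0 and 0 of 10 (10, 10, 0 and 3 adjusted over the list alone), and cold and heat genes 14, 14, 0 and 1 of 21 (16, 17, 3 and 5 adjusted over the list alone). The DnaJ gene LOC101166714 in the latter ranged 5.62-fold in summer with a peak at hour 15.1 and 6.57-fold in autumn with a peak at hour 16.8. ER stress genes had 8, 5, 1 and 0 of 20 (11, 5, 2 and 0 adjusted over the list alone). By Fisher's exact test on the mean rhythm these 6 lists held more rhythmic genes than the rest. The test treats genes as independent replicates, which they are not, so its p-values here and below are likely too small. Adjusted p was 4.1e-09 for activators (11 of 11 in the mean rhythm), 5.4e-12 for repressors (16 of 17), 9.9e-07 for PAR bZIP genes (8 of 8), 9.9e-07 for light and DNA repair (9 of 10), 2.1e-06 for cold and heat (13 of 21) and 0.0116 for ER stress (8 of 20). Fewer than elsewhere were rhythmic among ribosomal protein genes (0 of 88, adjusted p = 2.6e-05 by Fisher's exact test), oxidative phosphorylation genes (1 of 82, adjusted p = 6.1e-04) and proteasome genes (0 of 38, adjusted p = 0.0242).

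**Figure D3:**
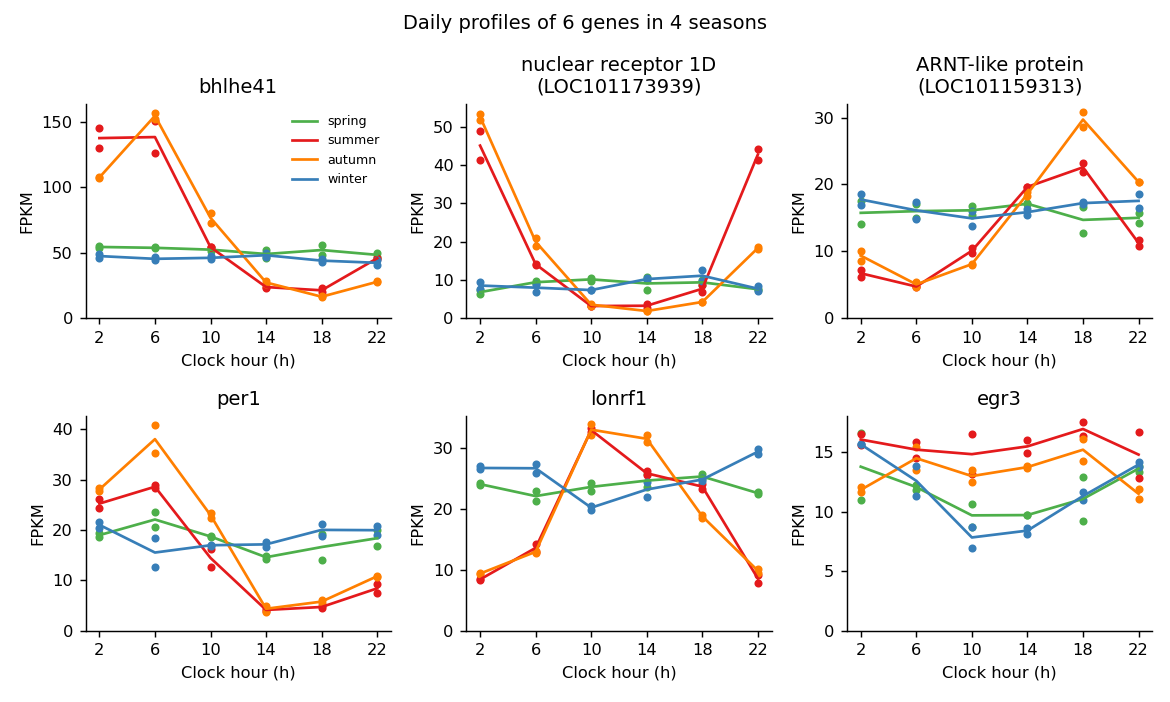
FPKM (y axes, starting at 0) against clock hour for 6 genes, with a point per library and a line through the mean of the 2 libraries of each hour, coloured by season. bhlhe41, the nuclear receptor 1D gene LOC101173939, the ARNT-like gene LOC101159313, per1 and lonrf1 rise and fall in summer and autumn, whereas egr3 has its largest amplitude in winter (0.46 on the log2 scale).

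**Figure D4:**
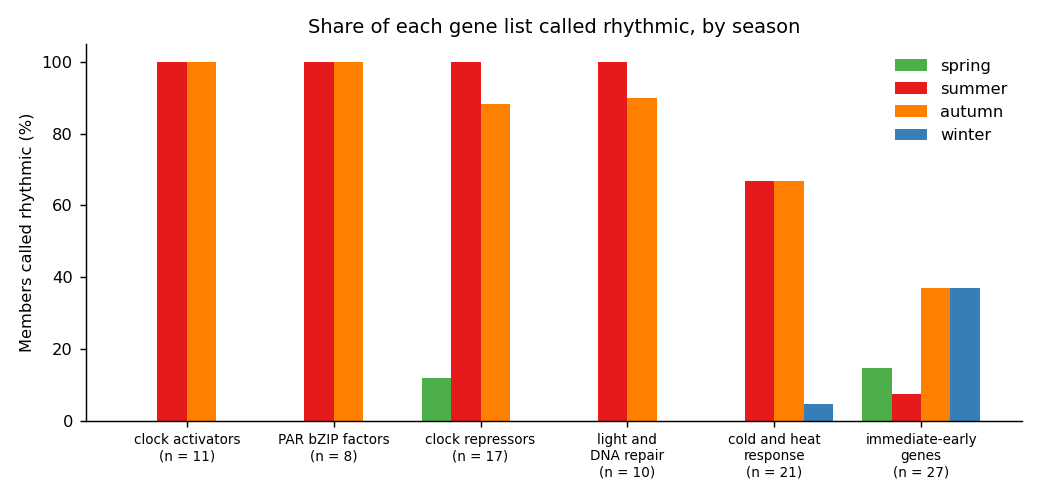
Percent of the tested members of 6 gene lists called rhythmic (y axis) in each season (bars, coloured), with the number of members under each list. All 11 clock activators are called in summer and in autumn and 0 in spring and winter, while immediate-early genes have 10 of 27 called in autumn and in winter.

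Over all 16622 genes, the mean rhythm was called in 2250 genes (13.5%). By season, 430 genes (2.6%) were rhythmic in spring, 2263 (13.6%) in summer, 2684 (16.1%) in autumn and 254 (1.5%) in winter; at an unadjusted p under 0.05 the counts were 3272, 4601, 4911 and 2846. Fitted on each season alone, summer had 1502 and autumn 1428, which turns their order, and with array weights winter had 1394. Summer and autumn shared 1138 rhythmic genes, against 365 with independence. Over all tested genes, rhythmic or not, the median amplitude was 0.09 in spring, 0.10 in summer, 0.11 in autumn and 0.09 in winter. In the shared genes autumn peaks came a median of 0.32 h after summer peaks, and 84.4% lay within 3 h. Spring and winter shared 30 rhythmic genes (6.6 with independence). All seasons use the same estimate of the spread for a gene, so calls in 2 seasons are not independent. Shared counts above these values therefore do not by themselves show shared rhythms. In all 4 seasons only LOC101160917 (leucine-rich repeat neuronal protein 4, named after its values were seen) was called. Peaks in summer were most frequent between hours 12 and 18 (787 of 2263), as in autumn (850 of 2684), and in spring and winter between hours 18 and 24 (163 of 430 and 83 of 254).

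The differences between seasons were themselves tested. For bhlhe41 the summer and winter curves differed with an adjusted p of 4.3e-20 and the spring and autumn curves with 5.0e-21. For LOC101173939 these values were 3.7e-16 and 2.4e-17, for per1 3.0e-11 and 1.8e-09 and for LOC101159313 1.7e-14 and 1.4e-16. LOC101159928, a thyrotroph embryonic factor of the PAR bZIP list, ranged 3.10-fold in summer and 3.44-fold in autumn, against 1.09-fold in spring and 1.002-fold in winter (adjusted p of the difference over any season 3.7e-15). Rhythms differed between any seasons in all 11 activators, all 17 repressors, all 8 PAR bZIP genes and all 10 light and DNA repair genes (11, 17, 8 and 10 adjusted over the list alone), in 14 of 21 cold and heat genes (17 adjusted over the list alone) and in 20 of 27 immediate-early genes (22 adjusted over the list alone). Over all genes, rhythms differed in 3573 (21.5%) between any seasons, in 1621 (9.8%) between summer and winter and in 2170 (13.1%) between spring and autumn. Fitted on spring and autumn libraries alone, the last count was 1229, and without the 3 spring libraries named above 1405.

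In spring and winter, other genes led by p. In spring the 5 smallest p belonged to LOC101162455 (a leucine-rich repeat and immunoglobulin protein, amplitude 0.42, SE 0.05, peak at hour 18.1, adjusted p = 1.2e-06), slitrk2 (0.34, hour 17.5), LOC101167411 (a SLIT and NTRK-like gene, 0.32, hour 17.9), lingo3 (0.49, hour 15.9), and the splicing-related gene scaf4 (0.27, hour 18.99). A CART gene, LOC100533500, ranged 4.00-fold with a peak at hour 19.2 (adjusted p = 0.009). The clock repressors LOC101172421 (2.71-fold, adjusted p = 0.0055) and LOC101174020 (1.89-fold, adjusted p = 0.0053) were the 2 clock-list genes called in spring. In winter the smallest p belonged to egr3, an activity-induced transcription factor (amplitude 0.46, SE 0.06, peak at hour 0.46, adjusted p = 7.4e-05), followed by the protein kinase gene LOC101162700 (0.20, hour 12.5), the ubiquitin ligase LOC101168073 (0.21, hour 12.2), the Notch target Her4 gene LOC100049439 (0.77, hour 20.2) and fbxl6 (0.28, hour 13.2). Somatolactin (LOC100049402) ranged 4.28-fold in winter with a peak at hour 9.6 (adjusted p = 0.009; 0.0619 without winter library 1 of clock hour 10).

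The spring and winter counts depend on the libraries and the fit. With 1 library left out, spring had 210 (without spring library 1 of clock hour 18) to 526, and winter 45 (without winter library 1 of clock hour 10) to 396 (without spring library 1 of clock hour 18). Fitted on spring libraries alone, 13 genes were rhythmic in spring, 7 of them among the 430, and LOC101162455 (adjusted p = 0.0606), LOC101167411 (0.0546), scaf4 (0.0662), lingo3 (0.0838) and LOC100533500 (0.0761) were no longer called, these being the highest values over their alternatives. Without the 3 spring libraries named above, 115 genes were rhythmic in spring and 402 in winter, and with a factor for clock hour 1044 and 462. In the main fit spring had more rhythmic genes than winter (430 against 254). That order turned with each season fitted alone (13 against 254), with array weights (333 against 1394) and without those 3 libraries. The main fit uses 1 estimate of the spread per gene for all seasons, so each count also rests on libraries of other seasons.

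Immediate-early genes, which neurons switch on with activity, had most of their rhythmic members in autumn and winter; whether peak hours differ between these seasons was not tested. In winter 10 of 27 were rhythmic (19 adjusted over the list alone), with peaks between hours 19.6 and 1.05, the junB gene LOC101164062 among them (2.60-fold, hour 21.6, adjusted p = 0.0051). In autumn 10 were rhythmic (15 adjusted over the list alone), 9 of them with peaks between hours 15.6 and 18.3. In summer 2 were rhythmic and in spring 4 (2 and 5 adjusted over the list alone). The list as a whole did not pass Fisher's exact test on the mean rhythm of the cosine (7 of 27, adjusted p = 0.191), but passed it with clock hour as a factor (21 of 27, adjusted p = 7.9e-11). The junB call was lost with the winter libraries alone (adjusted p = 0.0743) and without winter library 1 of clock hour 10 (0.0619), over a range up to 0.0743 among its alternatives.

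Pituitary hormone genes called rhythmic included lhb, cga and a thyrotropin beta gene, besides somatolactin in winter as given above. lhb ranged 2.11-fold in summer with a peak at hour 21.4 (amplitude 0.54, SE 0.12, adjusted p = 0.0059) and 1.88-fold in autumn with a peak at hour 0.88 (adjusted p = 0.023). The thyrotropin beta gene LOC105354380 ranged 6.44-fold in autumn with a peak at hour 23.9 (amplitude 1.34, SE 0.17, adjusted p = 1.2e-06), and its rhythm differed between spring and autumn (adjusted p = 0.00104). cga ranged 2.18-fold in autumn with a peak at hour 4.47 (adjusted p = 0.0019). Of 10 pituitary hormone genes, 0 were rhythmic in spring, 1 in summer, 4 in autumn and 1 in winter (0, 1, 4 and 1 adjusted over the list alone; Fisher's exact test on the mean rhythm, adjusted p = 1). The autumn call for lhb was lost with a factor for clock hour (adjusted p = 0.0732) and without autumn library 2 of clock hour 2, either library of clock hour 14 or library 2 of clock hour 22 (up to 0.102), the highest value among its alternatives.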

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

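The tests in this part were chosen before their results were seen, except 1 reading of the neuron markers that is named where it is used. Daily rhythms that differed between seasons call for a closer look. They number 3573 genes between any seasons, 1621 between summer and winter and 2170 between spring and autumn. In gene lists they cover 11 of 11 clock activators, 8 of 8 PAR bZIP genes, 17 of 17 clock repressors, 10 of 10 light and DNA repair genes and 20 of 27 immediate-early genes. Chance assignment of libraries is argued against for the counts over all genes, since 1 of 100 regroupings, the real one, reached each of them. That is the smallest share that 100 regroupings can give. Regrouped seasons also move real differences of rhythm into the spread between libraries, and the median regrouping gave 0 calls in each of these tests. The gap between the real and the other counts is therefore no measure of effect size. The highest other values were 1 for any season, 97 for summer and winter and 876 for spring and autumn.

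Clock genes had smaller daily rhythms in spring and winter than in summer and autumn. Over 36 clock-list genes the median amplitude was 0.16 in spring, 0.96 in summer, 0.91 in autumn and 0.12 in winter. The SE of each ratio below comes from resampling these genes, which are not independent replicates. A larger spread between libraries could cost calls but would not by itself lower a fitted amplitude, so a test of it does not bear on the amplitudes. The SD between libraries of a group was in any case similar, with a ratio of 1.011 (SE 0.068), spring and winter over summer and autumn. Mixed clock hours are argued against by a ratio of 0.2136 (SE 0.029) for the SD over the 12 libraries of a season. Low levels near the pseudocount are argued against by the levels themselves, with a median log2 level of 4.136 in spring and 4.179 in winter against 3.635 in summer and 3.803 in autumn, so that the amplitude ratio of 0.1557 (SE 0.032) with a pseudocount of 0.1 adds nothing to it. Fish or cells out of phase within a library, and smaller rhythms in each of them, stay open as untested, and season and batch cannot be told apart.

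Summer and autumn libraries stand apart from spring and winter libraries. Scaling, or a few genes that take most of the signal, is argued against because after quantile normalization the first component still held 42.6% of variance and separated all 48 libraries. A different share of neurons alone would move neuron markers against those of the other cell types, but the neuron list was higher by 0.275 (SE 0.034) with the myelin list 0.51 (SE 0.20) and the red blood cell list 0.69 (SE 0.29) higher too. The outcome written beforehand to exclude it, other lists going both ways beyond their spread, did not occur, and this reading was added after the values were seen. Radial glia markers were at 0.18 (SE 0.10), microglia and macrophage markers at 0.18 (SE 0.07) and endothelial markers at -0.001 (SE 0.06), against 0.06 for all genes. Each SE comes from resampling list genes and leaves out the spread between libraries. A change in the share of myelin or blood may contribute and stays open, and season and batch cannot be told apart.

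The level of lhb was higher in summer than in winter, by 4.22 on the log2 scale. More pituitary tissue in the summer libraries would raise the other pituitary hormone genes by a similar amount. The median over 7 of them, gonadotropin subunits left out, was 0.07231, with a range from -1.115 to 1.612. A change of lhb itself or of the number of cells that make it may account for the difference, as a hypothesis, and season and batch cannot be told apart.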

How the results depend on the processing

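Leaving out 3 spring libraries together was chosen only after the results were seen; the other alternatives were planned. The 7 season counts moved by less than 1.5 times under every alternative run (any season 14907 to 19368, summer against winter 12230 to 15559, spring against autumn 11506 to 14761). Counts of rhythms in spring and winter moved most, and for each move below the cause was not tested unless stated. With array weights, 1394 genes were rhythmic in winter, among them all 254. Fitted on a season alone, 13 genes were rhythmic in spring (7 shared with the 430), 1502 in summer and 1428 in autumn. In winter 254 were called, 119 of them shared. Fitted on spring and autumn alone, 1229 rhythms differed between them (1196 shared). These fits have fewer libraries and residual degrees of freedom, and use the spread of the fitted seasons alone. The loss of libraries is the same for each season, so it cannot by itself account for 13 in spring beside 254 in winter. With clock hour as a factor, 1044 were rhythmic in spring and 462 in winter (342 and 148 shared), and 12 lists in place of 9 passed Fisher's exact test on the mean rhythm. The 3 added were immediate-early (adjusted p = 7.9e-11 against 0.191), glucocorticoid response (2.3e-04 against 0.0662) and microglia and macrophage (0.0224 against 1). With a replicate block, 150 were rhythmic in winter, although library numbers do not pair the libraries (correlation of the 36 same-hour pairs -0.163 to 0.293, median -0.005). Camera with a preset correlation called 46 list tests, a setting that fixes the correlation between genes by construction.

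Leaving out 1 library gave 210 to 526 rhythmic genes in spring and 45 to 396 in winter. The spring count was 235 without spring library 1 of clock hour 6, 217 without library 2 of clock hour 10 and 210 without library 1 of clock hour 18. The winter count was 396 without spring library 1 of clock hour 18. Among winter libraries, it was 118 without library 1 of clock hour 2, 45 and 82 without libraries 1 and 2 of clock hour 10, 118 and 133 without libraries 1 and 2 of clock hour 14, and 142 and 111 without libraries 1 and 2 of clock hour 22. Without the 3 spring libraries high on the second component, 115 were rhythmic in spring, 402 in winter, and 1405 rhythms differed between spring and autumn. Each season has its own curve, so spring libraries enter the winter test only through the spread shared by all seasons and its degrees of freedom. The winter counts of 396 and 402 therefore come from that shared spread. For the other moves the cause was not tested. Of 1800 checks on 182 results of 95 named genes, 1778 stayed on their side of the threshold, 22 were lost and 0 reversed. Leave-one-out entered by the lowest and highest value of each result alone, so the 22 leave out most single-library losses given below. Many results were chosen for large folds or small p in these same data, so staying called was likely beforehand. Among those lost, the rhythm of egr1 in spring (adjusted p 1.2e-05 to 0.086 over its alternatives) was lost without any 1 of the 12 spring libraries. That of egr1 in winter (3.7e-08 to 0.237) was lost without library 1 of clock hour 2 or any library of clock hours 10 and 22. That of the FKBP5 gene LOC101157675 in spring (1.1e-04 to 0.142) was lost without library 1 of clock hours 2 or 6, library 2 of clock hours 10 or 22, or any library of clock hours 14 and 18. Depth per library is unknown, so what it limits could not be worked out.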

Other observations

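The tests on regroupings in this part were planned, and no test was chosen only after a result was seen. Other gene lists had members called between seasons, and none of those given here passed the camera test. Of 22 glucocorticoid response genes, 4 were higher and 11 lower in summer than in winter (4 and 11 adjusted over the list alone; camera adjusted p = 0.576). Among them klf9, a transcription factor induced by glucocorticoids, was 2.21-fold lower in summer. Of 5 melatonin genes, 3 were higher in summer than in winter and 0 lower (3 and 0 adjusted over the list alone; camera adjusted p = 0.445). Of 48 skeletal muscle markers in the file, only 8 passed the filter and were tested. Among these 8, 5 were higher and 1 lower in summer than in winter (5 and 1 adjusted over the list alone, camera adjusted p = 0.445), with mb, the oxygen store of muscle, 2.18-fold higher. Cell cycle genes were 7 higher and 5 lower of 14 (7 and 5 adjusted over the list alone; camera adjusted p = 0.701) and, between spring and autumn, 1 higher and 10 lower in spring (1 and 10 adjusted over the list alone; camera adjusted p = 0.445). Of 15 opsin genes, 2 were higher and 5 lower in summer (2 and 5 adjusted over the list alone; camera adjusted p = 0.69), and of 21 interferon response genes 9 were higher and 5 lower (9 and 5 adjusted over the list alone; camera adjusted p = 0.99).

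The glucocorticoid list had 5 rhythmic members in spring, 7 in summer, 10 in autumn and 1 in winter (11, 9, 12 and 1 adjusted over the list alone).

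In each of the other results, only the real one of 100 regroupings was as large, the smallest share that 100 regroupings can give. For the tests of genes this argues against chance assignment of the libraries, but it does not tell season from batch. Regrouped seasons move the season difference into the spread between libraries, and the median regrouping gave 0 calls in each season test. The real count and the highest other count were 15117 and 12 for any season, 12451 and 9656 for summer and winter, 12038 and 10812 for spring and autumn, 12266 and 9335 for spring and summer, 7245 and 5321 for summer and autumn, 11914 and 8439 for autumn and winter, and 8204 and 1937 for winter and spring. For rhythms they were 430 and 97 in spring, 2263 and 743 in summer, 2684 and 946 in autumn, 254 and 9 in winter and 2250 and 3 for the mean. For gene lists they were 2 and 1 between seasons and 9 and 0 in the daily rhythm. In the gene tests regrouped hours left at most 3 genes in the mean rhythm, so hardly any list could pass Fisher's exact test. Regrouped seasons also widen the spread that camera uses. The list counts therefore do not decide on chance.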
